A study of Mus musculus with 3 samples.

How the data were processed

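Polyadenylated RNA from cultures of bone-marrow-derived macrophages of C57BL/6J mice was sequenced in 3 libraries, all labelled with 100 ng/ml lipid A for 0 minutes. Each library came with a gene table, 2 transcript tables and a list of the files they were derived from. Per the file headers the gene table and 1 transcript table are in the format of RSEM, a program that shares reads among transcripts by likelihood. The other transcript table is in the format of kallisto, which assigns reads without a full alignment. The deposited lists give the genome build mm10 and the GENCODE annotation M21, say that the RSEM-format tables were made from alignments to the transcriptome and the kallisto-format tables directly from the reads, and name 6, 6 and 4 read files for replicates 1, 2 and 3. The aligner, the program versions and whether counting used strand are not given in the sources used here.

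Expected counts, per the file headers, are estimates that need not be whole, because reads that match several transcripts are divided among them. The deposited gene tables also hold posterior mean counts, which served as an alternative. Estimated counts in the kallisto-format tables were deposited by the authors per transcript. TPM, per the file headers, are transcript abundances that are scaled after division by effective length to the same sum in each library. FPKM values in the deposited gene tables are fragments per kilobase, scaled to library size. The percent of a gene taken by each transcript is deposited in the RSEM-format table; shares were recomputed here from TPM so that both tables were treated alike.

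All 55536 genes of the gene tables were found in annotation M21, from which symbols, gene types and coordinates (1-based) were taken. Of genes that share a symbol, the more abundant was used. The tables also hold 26248 numbered entries that name no gene and had 0 counts, and 97 spike-in entries. Of the spike-in sequences only phiX174 had counts in the gene tables, with 0.131%, 0.122% and 0.0843% of the total in replicates 1, 2 and 3. These entries were left out of library sizes and tests. Genes that share reads with close copies are uncertain, because the split between copies rests on the authors' estimate. The library totals ranged from 27946070 to 53447437 counts. Wilson intervals at 95% and the limit of 3 counts for a count of 0 cover counting error only, since reads without molecular identifiers are not independent molecules.

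The libraries were placed in 1 group from their labels. With no second group there was no contrast to test and no paired analysis. Expected counts were rounded to whole numbers; CPM are counts scaled to library totals of equal size. With edgeR 4.0.16 (limma 3.58.1, R 4.3.3) genes were filtered by filterByExpr, scaled by TMM factors and fitted with an intercept only by glmQLFit in its legacy form. The upper-tail F test set each gene's quasi-dispersion against the prior fitted over all genes, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation is the square root of the common dispersion. The test was tried on simulated counts with the real means and library sizes, in which 200 genes were changed in 1 library. With dispersions on the fitted trend it recovered 14.7% of genes changed 8-fold, 95.4% of those changed 32-fold and 50.8% at the largest change tried. With dispersions also spread between genes it recovered 0% at each size. Those counts were more variable than the data, with a coefficient of 0.467 with no gene changed, against 0.398 in the data. The 0% may therefore be too low. The test called 0 unchanged genes in every simulation.

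Levels and spreads were summarised over 43 gene lists for macrophage functions and for other cells of bone marrow. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 20 genes of highest mean TPM, the 3 highest members and the lowest member of each list, any member of the TLR4, NF-kB, early, late and sex-linked lists needed to describe them, and for transcripts the 6 genes of the TLR4, NF-kB, IRF and STAT lists with at least 10 TPM and the lowest dominant share, with Il1rn, Irak2, Myd88, Nfkb1 and Tlr4. Results of 1 gene that the rule names are not reported. Genes named outside the rule are marked as chosen after their values were seen. A list's level is the median over members of the mean TPM. A list's spread is the median over members of quasi-dispersion over prior. A list's ratio in a library is the median over members of the log2 ratio of TMM-scaled counts (prior count 0.5) to the geometric mean of the other libraries. Percentiles come from 10000 random lists matched on mean expression in 25 bins (seed 1) and describe these libraries; they are not tests. The median log2 ratio of all tested genes was 0.00, 0.00 and 0.01 in replicates 1, 2 and 3 on the TMM scale and 0.10, 0.12 and -0.23 on the log2 TPM scale with pseudocount 1.

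Alternatives were other normalizations, other filters on low counts, DESeq2 1.42.0 dispersion outliers, a robust prior, posterior mean counts, other TPM thresholds, FPKM, TPM without mitochondrial genes, the kallisto-format table, pseudocounts of 1 and 0.1 on the log2 TPM scale, and each replicate left out in turn. Leaving out a library from a list's ratio, and removing a trend on GC content and transcript length, were added after the data were seen. GC content and length came from the most abundant transcript of each gene and were known for 100.0% of tested genes (11882 of 11886). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.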

Results

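Polyadenylated RNA was sequenced from macrophages grown from the bone marrow of C57BL/6J mice, a laboratory strain. The labels give a lipid A dose of 100 ng/ml and a time of 0 minutes. Lipid A is the part of bacterial lipopolysaccharide that Toll-like receptor 4 (TLR4) recognises, so time 0 is the starting level of a stimulation. There was 1 group of 3 libraries, called biological replicates 1, 2 and 3 in the labels, and no second group to compare with. The labels give each library its own biosample and all of them the same donor record, and do not say whether the cultures came from separate animals, so the spread between libraries can be partly technical. The design therefore gives the level of each gene before stimulation and its spread between replicates.

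The gene tables held 27946070, 29779410 and 53447437 expected counts in replicates 1, 2 and 3. A count of 0 allows up to 3 counts, or 0.107, 0.101 and 0.0561 CPM, in these libraries. Protein-coding genes took 88.5%, 96.0% and 93.4% of the counts. The ribosomal RNA gene CT010467.1 (chromosome 17, 39846353 to 39848827, minus strand, build mm10) took 9.75% of replicate 1 (95% Wilson interval 9.74 to 9.77), 1.88% of replicate 2 (1.88 to 1.89) and 2.50% of replicate 3 (2.50 to 2.51). Transcripts of the mitochondrial genome took 1.84% (1.84 to 1.85), 2.24% (2.23 to 2.24) and 6.98% (6.98 to 6.99). Transcripts of cytosolic ribosomal protein genes took 2.12% (2.12 to 2.13), 2.25% (2.24 to 2.25) and 1.29% (1.28 to 1.29).

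At a threshold of 1 TPM, 11591, 11648 and 11135 genes were detected in replicates 1, 2 and 3. Of these, 10548 passed in every library, and 9875 of the 10548 were protein coding. The most abundant nuclear messenger RNAs were those of the ferritin subunits, which store iron, with Fth1 at 27685 ± 9309 TPM and Ftl1 at 22501 ± 10446 TPM (SD, n = 3). Next came the lysozyme gene Lyz2 at 18742 ± 9608 TPM, the membrane glycoprotein gene Gpnmb at 16178 ± 13172 TPM, the lysosomal protease genes Ctsd at 13002 ± 2056 TPM and Ctsb at 10697 ± 4138 TPM, Psap at 12802 ± 4272 TPM and the apolipoprotein gene Apoe at 12011 ± 2749 TPM. B2m, the light chain of MHC class I, stood at 9004 ± 1943 TPM, Selenop at 8653 ± 4857 TPM and Tmsb4x at 8210 ± 4118 TPM. The other 9 of the 20 genes of highest mean were CT010467.1 at 44049 ± 42351 TPM, 5 mitochondrial genes led by mt-Atp8 at 35490 ± 20699 TPM, and 3 nuclear copies of mitochondrial sequence on chromosome 1 led by Gm28661 at 18633 ± 15171 TPM. Values of these mitochondrial genes and their nuclear copies are uncertain because the copies share reads.

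The cultures carried the transcripts of macrophages. The macrophage identity list had a median of 383 TPM, and 20 of its 21 members were at 1 TPM or more in every library. Cd68, a lysosomal membrane protein of macrophages, stood at 3935 ± 1671 TPM and the signalling adaptor Tyrobp at 2800 ± 937 TPM. Csf1r, the receptor for the growth factor M-CSF, stood at 892 ± 352 TPM and Adgre1, which encodes F4/80, at 522 ± 161 TPM; these 2 genes were chosen after their values were seen. The lowest member was the fractalkine receptor Cx3cr1 at 1.15 ± 1.05 TPM. All 26 members of the lysosome list (median 770 TPM) and all 17 scavenger, Fc and phagocytic receptors (median 275 TPM) were at 1 TPM or more in every library, with Fcgr3 at 843 ± 128.1 TPM. Among scavenger receptors Cd36 differed most in level, at 1133, 108 and 635 TPM in replicates 1, 2 and 3. The complement list had 9 of 11 members at that level and a median of 384 TPM, which was 204 TPM without replicate 1, and C1qb led it at 3075 ± 727 TPM.

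The receptor complex and relay proteins for lipid A were transcribed at time 0. Of the 25 TLR4 signalling components, 24 were at 1 TPM or more in every library, and the list median was 28.9 TPM (library medians 31.5, 31.2 and 29.98, SD 0.783, n = 3). Tlr4 itself (chromosome 4, 66827584 to 66930284, plus strand) stood at 56.6 ± 9.75 TPM and its partner Ly96, also called MD-2 (chromosome 1, 16688051 to 16709611, plus strand), at 56.3 ± 17.1 TPM. The co-receptor Cd14 (chromosome 18, 36725067 to 36726798, minus strand) stood at 125 ± 62.8 TPM. Transcripts of the adaptor Myd88 were at 53.9 ± 21.4 TPM, of Ticam1 (TRIF) at 19.4 ± 5.05 TPM, of the kinases Irak1 at 50.6 ± 2.13 TPM and Tbk1 at 64.5 ± 11.98 TPM, and of the ubiquitin-conjugating enzyme Ube2n at 130 ± 39.3 TPM. The lipopolysaccharide-binding protein gene Lbp was the lowest, at 1.47 ± 0.892 TPM. Other Toll-like receptors had 11 of 13 members at 1 TPM or more in every library (median 51.9 TPM), led by the trafficking protein gene Unc93b1 at 486 ± 183 TPM and by Tlr13 at 205 ± 80.9 TPM, while Tlr12 was at 0.190 ± 0.252 TPM.

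The transcription factors that act downstream of TLR4 were present as well. All 11 genes of the NF-kB family and its inhibitors were at 1 TPM or more in every library, with a median of 17.0 TPM. Nfkb1 stood at 51.3 ± 13.5 TPM and the inhibitor Nfkbia at 50.7 ± 27.7 TPM. Rela, which encodes the p65 subunit, was at 40.3, 53.1 and 190.5 TPM in replicates 1, 2 and 3, and its transcripts differed too, as given below. The IRF and STAT factors had 14 of 16 members at that level (median 52.4 TPM), with Irf7 at 173 ± 107 TPM and Irf5 at 136 ± 23.5 TPM. Negative regulators of TLR signalling had 13 of 15 (median 21.1 TPM), with Atf3, a repressor of inflammatory genes, at 275 ± 187 TPM and the RNA-binding protein Zfp36 at 61.3 ± 7.72 TPM. The inflammasome list had 14 of 14 (median 28.4 TPM), with Casp1 at 120 ± 25.5 TPM.

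Genes that lipid A is known to induce early were largely transcribed at time 0, and those known to be induced late were largely not. The early inflammatory effectors had a median of 30.3 TPM with 15 of 17 members at 1 TPM or more in every library, and the late effectors a median of 0.537 TPM with 4 of 17. Without replicate 2 the late median was 0.330 TPM. Chemokine genes led the early list, with Ccl3 at 230 ± 71.9 TPM and Ccl4 at 186 ± 127 TPM. The neighbouring monocyte chemoattractant genes Ccl2 (chromosome 11, 82035571 to 82037453, plus strand) and Ccl7 (chromosome 11, 82045712 to 82047525, plus strand) were highest in replicate 1, at 731 and 930 TPM, against 66.0 and 62.5 TPM in replicate 2 and 39.9 and 46.1 TPM in replicate 3. The cytokine gene Tnf stood at 30.3 ± 15.6 TPM and Il1b at 8.42 ± 4.53 TPM, while Ptgs2, which encodes cyclooxygenase-2, was at 0.657 ± 0.341 TPM and Cxcl3 at 0.273 ± 0.136 TPM. Among late effectors Ccl5 stood at 121 ± 70.5 TPM, Saa3 at 53.6 ± 17.1 TPM, Acod1 at 15.4 ± 10.6 TPM and Lcn2 at 7.64 ± 4.76 TPM. Il6 (0.293 ± 0.145 TPM), Ifnb1 (0.193 ± 0.0379 TPM) and Csf3 (0.0300 ± 0.0265 TPM) were near the limit of detection, with 2, 2 and 1 counts in replicate 1. Nos2, the inducible nitric oxide synthase, was at 0.673 ± 0.595 TPM. The immediate early genes had 13 of 16 members at 1 TPM or more in every library (median 12.9 TPM), led by Jun at 97.6 ± 22.2 TPM, with Fosl1 lowest at 0.0267 ± 0.0462 TPM. No test compared these lists, whose members differ in basal level for many reasons.

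**Figure D1:**
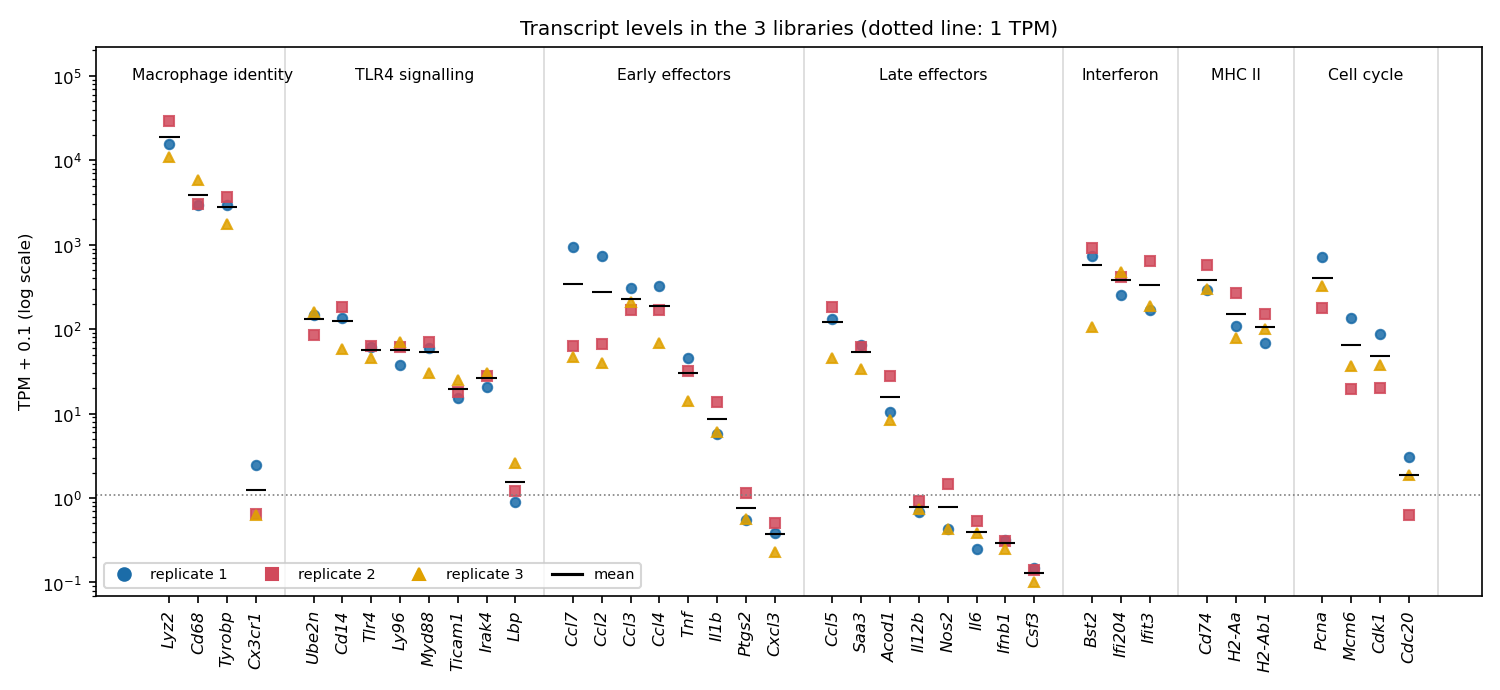
Level of single genes in replicates 1, 2 and 3 on a log axis (TPM plus 0.1), by gene list, with the mean of the 3 libraries as a black line and 1 TPM as a dotted line. Tlr4 and Ly96 lie at 56.6 and 56.3 TPM in the mean, the late effectors from Il12b to Csf3 lie below 1 TPM in the mean, and Ccl7 and Ccl2 are highest in replicate 1.

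Interferon-stimulated genes were transcribed in every library and at unequal levels. Their list had 36 of 38 members at 1 TPM or more in every library and a median of 69.0 TPM, with library medians of 30.5, 128.8 and 28.4 TPM in replicates 1, 2 and 3. Without replicate 2 the median was 29.3 TPM. Bst2, which encodes tetherin, stood at 581 ± 420 TPM, the DNA-sensor family gene Ifi204 at 383 ± 114 TPM and Ifit3 (chromosome 19, 34583531 to 34588731, plus strand) at 332 ± 269 TPM. Ifi44l had no counts in the gene tables. The 7 interferon receptors and kinases were at 1 TPM or more in every library, with Ifnar2 at 177 ± 42.5 TPM. Their library medians were 69.7, 70.5 and 70.7 TPM, but on TMM-scaled counts 6 of the 7 were lowest in replicate 1. Their median log2 ratio to the other libraries was -0.56 there, against -0.09 ± 0.25 (SD) for matched lists. MHC class II genes had 6 of 8 members at 1 TPM or more in every library. Their median was 65.9 TPM (39.2 TPM without replicate 2), and the invariant chain Cd74 led them at 386 ± 159 TPM. MHC class I genes had 11 of 11 and a median of 97.2 TPM (57.7 TPM without replicate 2), with H2-D1 at 3063 ± 1292 TPM and H2-K1 at 2488 ± 937 TPM. H2-D1 and H2-K1 share sequence, as do Ifi204, Gbp and Ifit family members, so their split is uncertain.

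Receptors for cytokines had 16 of 18 members at 1 TPM or more in every library (median 55.0 TPM), led by Il10rb at 321 ± 43.2 TPM, and chemokine and chemoattractant receptors had 7 of 11 (median 10.4 TPM, 6.16 TPM without replicate 1), led by Cxcr4 at 80.7 ± 63.4 TPM. Genes of alternative activation, the programme that interleukin-4 induces, had 6 of 12 (median 2.15 TPM): Tgfb1 stood at 291 ± 30.4 TPM and Ccl17 had no counts. Lipid handling and LXR genes had 14 of 15 (median 124 TPM), with the fatty acid-binding protein gene Fabp5 at 4402 ± 535 TPM. Sterol synthesis genes had 18 of 18 (median 38.2 TPM), led by Msmo1 at 131 ± 63.0 TPM. Cell cycle genes had 21 of 24 (median 10.5 TPM), led by the replication clamp Pcna (chromosome 2, 132249162 to 132253314, minus strand) at 409 ± 283 TPM. Glycolysis and hypoxia genes had 15 of 16 (median 40.5 TPM; Pkm at 653 ± 370 TPM), stress response genes 10 of 16 (median 18.0 TPM; Hspa5 at 602 ± 33.9 TPM), osteoclast genes 6 of 11 (median 3.71 TPM; Atp6v0d2 at 277 ± 237 TPM), and metalloproteinases and inhibitors 7 of 12 (median 15.3 TPM; Timp2 at 361 ± 103 TPM). The housekeeping list had 12 of 12 (median 496 TPM; Eef1a1 at 5380 ± 568 TPM), cytosolic ribosomal proteins 78 of 82 (median 713 TPM; Rps24 at 2579 ± 246 TPM) and mitochondrially encoded genes 13 of 13 (median 3580 TPM, 1727 TPM without replicate 3).

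Markers of other cells that a bone marrow culture can hold were mostly near 0. Of 120 markers in 12 lists, 78 were below 1 TPM in every library and 26 at 1 TPM or more in every library. The neutrophil list had 4 of 12 at that level: S100a9 at 86.9, 20.1 and 183 TPM in replicates 1, 2 and 3, S100a8 at 65.0, 12.3 and 83.0 TPM, Ngp at 13.8, 1.95 and 57.5 TPM, and Ltf, chosen after its values were seen, at 3.97, 1.33 and 10.7 TPM, while Ly6g had no counts. Monocyte markers had 4 of 8, led by Ms4a4c at 79.5 ± 65.0 TPM, with Ly6c2 at 9.30 ± 3.74 TPM. Megakaryocyte markers had 3 of 7, of which Pf4 was at 2441, 317 and 564 TPM and Ppbp at 6.73 ± 4.59 TPM. T and NK cell markers had 1 of 13, which was Cd4 at 85.3 ± 55.5 TPM, and the next member, Klrd1, was at 0.650 ± 0.217 TPM. Tissue-resident macrophage markers had 5 of 14, led by Cd5l at 530 ± 166 TPM. B cell markers had 2 of 9, of which Ighm was at 14.9 ± 13.4 TPM, dendritic cell markers 1 of 8 (Batf3 at 4.18 ± 2.06 TPM), erythroid markers 1 of 9 (Epor at 4.78 ± 0.991 TPM), stromal and osteoblast markers 1 of 15 (Runx2 at 1.59 ± 0.320 TPM), endothelial markers 2 of 7 (Vwf at 17.9 ± 13.0 TPM), progenitor markers 2 of 8 (Ly6a at 46.2 ± 56.3 TPM), and mast cell, basophil and eosinophil markers 0 of 10 (Prg2 highest at 0.437 ± 0.599 TPM).

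The female-specific transcript Xist (chromosome X, 103460366 to 103483254, minus strand) stood at 78.7 ± 0.690 TPM (n = 3). The genes Ddx3y, Eif2s3y, Kdm5d and Uty of the Y chromosome had 0 counts in every gene table, which allows up to 3 counts in each library. In the other transcript table Kdm5d had 14.6, 20.1 and 25.3 estimated counts, Uty 6.16, 9.62 and 11.98, Ddx3y 4, 17 and 9, and Eif2s3y 0, 1 and 2, against 24398, 23634 and 35212 for Xist. The labels record no sex.

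Across the 10548 detected genes, which are not independent replicates, the Pearson correlation was taken on log2 TPM with pseudocount 1. It was 0.926 between replicates 1 and 2, 0.914 between 1 and 3, and 0.919 between 2 and 3. After removal of the median ratio, 17.0%, 21.9% and 20.5% of these genes were over 2-fold apart in the 3 pairs. The biological coefficient of variation was 0.398 over 11886 tested genes, with a jackknife standard error of 0.0142, and its trend had a median of 0.497 below 4 CPM and 0.340 above 64 CPM. Against genes of like abundance, edgeR called 0 genes as more variable after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.970. In the same F test 545 genes had an unadjusted p under 0.05, where 594 were expected by chance. The prior was fitted to the same genes, so this count cannot show whether genes vary in excess. In the simulations the share stayed between 3.92% and 5.12%, with or without changed genes. DESeq2 marked 9 genes as dispersion outliers, edgeR without a filter on low counts called 146, and edgeR without replicate 2 called 7. In simulated counts with dispersions on the fitted trend, the test recovered 14.7% of genes changed 8-fold in 1 library and 95.4% of those changed 32-fold. With dispersions also spread between genes it recovered 0% of genes changed 8-fold or more. Those counts were more variable than the data, with a coefficient of 0.467 with no gene changed. The 0 calls therefore do not show that no gene varied. The genes of smallest unadjusted p, chosen after their values were seen, included Dusp6 (chromosome 10, 99263231 to 99267489, plus strand) at 113, 4.99 and 3.39 TPM in replicates 1, 2 and 3, Ccl7, Uhrf1 at 44.9, 1.95 and 8.83 TPM, and Cxcl10 (chromosome 5, 92346638 to 92348889, minus strand) at 24.6, 273 and 20.2 TPM.

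Genes of certain lists moved together between replicates. Interferon-stimulated genes were highest in replicate 2 for 36 of 37 tested members, and their median log2 ratio to the other libraries was 1.68 in replicate 2, -0.92 in replicate 1 (-0.34 against replicate 3 alone) and -0.44 in replicate 3 (0.34 against replicate 1 alone). Cxcl10 and Gbp2, chosen after their values were seen, were at 273 and 208 TPM in replicate 2, against 24.6 and 17.4 TPM in replicate 1. Ifi204 was the exception, with 473 TPM in replicate 3 and 420 TPM in replicate 2. The MHC class II list (1.05, 8 of 8 members highest in replicate 2), the MHC class I list (1.05, 9 of 11), the NF-kB list (0.88, 10 of 11) and the IRF and STAT list (0.60, 11 of 15; 0.34 against replicate 3 alone) were also highest in replicate 2. Early effectors had a median of 0.39 there, which was 0.83 against replicate 3 alone and 0.13 against replicate 1 alone, and late effectors 0.32 (0.48 against replicate 1 alone). Markers of monocytes were at 0.82 in the same library (-0.098 against replicate 3 alone) but were split, with 4 of 8 tested members highest and 3 lowest there. Few genes were tested for the other marker lists: neutrophils were at -3.17 (4 genes), megakaryocytes at -1.72 (5 genes) and endothelial cells at 1.39 (3 genes). On the log2 TPM scale with pseudocount 1 these ratios were -2.54, -0.34 and 1.36, so that of the megakaryocyte markers depended on the scale. The spread of the interferon-stimulated genes was 5.83 times its prior, above every one of 10000 lists matched on expression, and 0.512 without replicate 2.

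With all 3 libraries, cell cycle genes varied most among the lists fixed for the macrophages themselves. Their median log2 ratio to the other libraries was 1.56 in replicate 1, -2.19 in replicate 2 and 0.56 in replicate 3; 18 of 24 members were highest in replicate 1 and 23 of 24 lowest in replicate 2. Pcna was at 725, 178 and 325 TPM, the replicative helicase subunit Mcm6 at 137, 19.5 and 36.4 TPM, the mitotic kinase Cdk1 at 86.7, 20.1 and 37.9 TPM and Cdc20 at 3.00, 0.530 and 1.77 TPM in replicates 1, 2 and 3. The spread was 7.35 times its prior, above all matched lists, and 3.85 without replicate 1, 1.25 without replicate 2 and 11.2 without replicate 3. The rank turned with the first 2 of these: interferon-stimulated genes had 7.68 without replicate 1, and immediate early genes at least 1.68 with any replicate left out. Set against replicate 3 alone the median cell cycle ratio of replicate 1 was 0.71, and against replicate 2 alone it was 2.73. Replicate 1 also had the highest share of the ribosomal RNA gene, its monocyte markers had a median ratio of -1.15 over 8 tested genes, and its progenitor markers had a median ratio of -0.54 over 4 tested genes (0.20 against replicate 3 alone and -1.06 against replicate 2 alone).

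**Figure D2:**
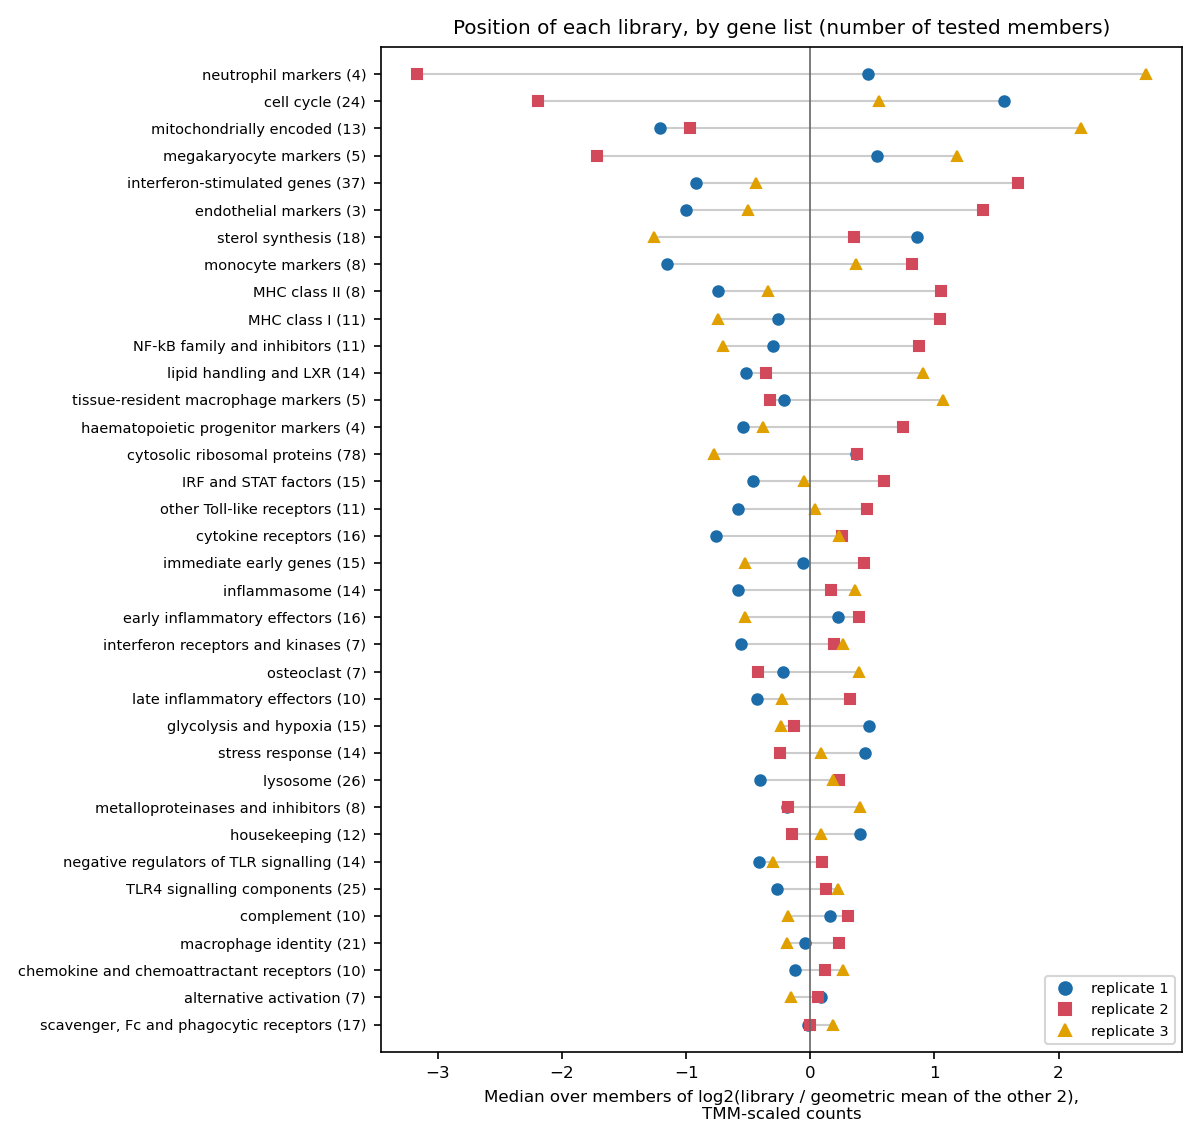
Median over the tested members of each gene list of the log2 ratio of 1 library to the geometric mean of the other libraries, from TMM-scaled counts, with 1 symbol per replicate and the number of tested members in brackets. Interferon-stimulated genes lie at 1.68 in replicate 2, cell cycle genes at 1.56 in replicate 1 and -2.19 in replicate 2, and macrophage identity genes between -0.19 and 0.23.

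Macrophage identity genes and lysosomal genes had the lowest spread of the 36 lists with at least 3 tested genes. The spread of the identity genes was 0.421 times its prior, at percentile 3.87 of matched lists. Their median log2 ratios were -0.04, 0.23 and -0.19 in replicates 1, 2 and 3. The ratio in replicate 3 lay over 2 SDs below matched lists (0.23 ± 0.15). The spread of the lysosome list was 0.455 times its prior, at percentile 3.64 (0.0617 without replicate 1). Of the lysosomal genes 20 of 26 were lowest in replicate 1, with a median log2 ratio of -0.41, within 2 SDs of matched lists (-0.14 ± 0.16), and -0.22 on the log2 TPM scale. The TLR4 components had a spread of 1.32 times the prior, at percentile 94.8 (0.209 without replicate 3), and median log2 ratios of -0.26, 0.13 and 0.23 in replicates 1, 2 and 3. Replicates 2 and 3 set against each other differed by 0.048 in favour of replicate 3, which turns the sign of replicate 2, and on the log2 TPM scale the ratios were -0.040, 0.20 and 0.044. The spread of the early effectors was at percentile 99.2 and that of the late effectors at percentile 99.4, both lower without replicate 2, at 0.285 and 0.189 times the prior. In all, 17 of the 36 lists lay above percentile 99 and 2 below percentile 5.

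Cytosolic ribosomal protein genes were lowest in replicate 3 for 63 of 78 tested members, with a median log2 ratio of -0.77, against 0.36 in replicate 1 (-0.0039 against replicate 2 alone) and 0.38 in replicate 2 (0.77 against replicate 3 alone). Rplp1, a protein of the ribosomal stalk, was at 3371, 3382 and 805 TPM in replicates 1, 2 and 3 and Rps27 at 1783, 3008 and 790.2 TPM, while Rps24 was at 2382, 2500 and 2855 TPM. In replicate 3 mitochondrially encoded genes had a median ratio of 2.18 and neutrophil markers, with 4 tested genes, 2.70 (1.49 against replicate 1 alone). Over 5 tested genes each, tissue-resident macrophage markers had 1.07 there and megakaryocyte markers 1.18 (-0.00899 on the log2 TPM scale with pseudocount 1). The spread of the ribosomal protein list was 1.65 times its prior, above all matched lists, and 0.0735 without replicate 3. Replicate 3 was also the deepest library, came from 4 read files where the others came from 6, and had a shorter effective-length offset of 246 bases against 259 in replicates 1 and 2, so its library and its biology cannot be separated.

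**Figure D3:**
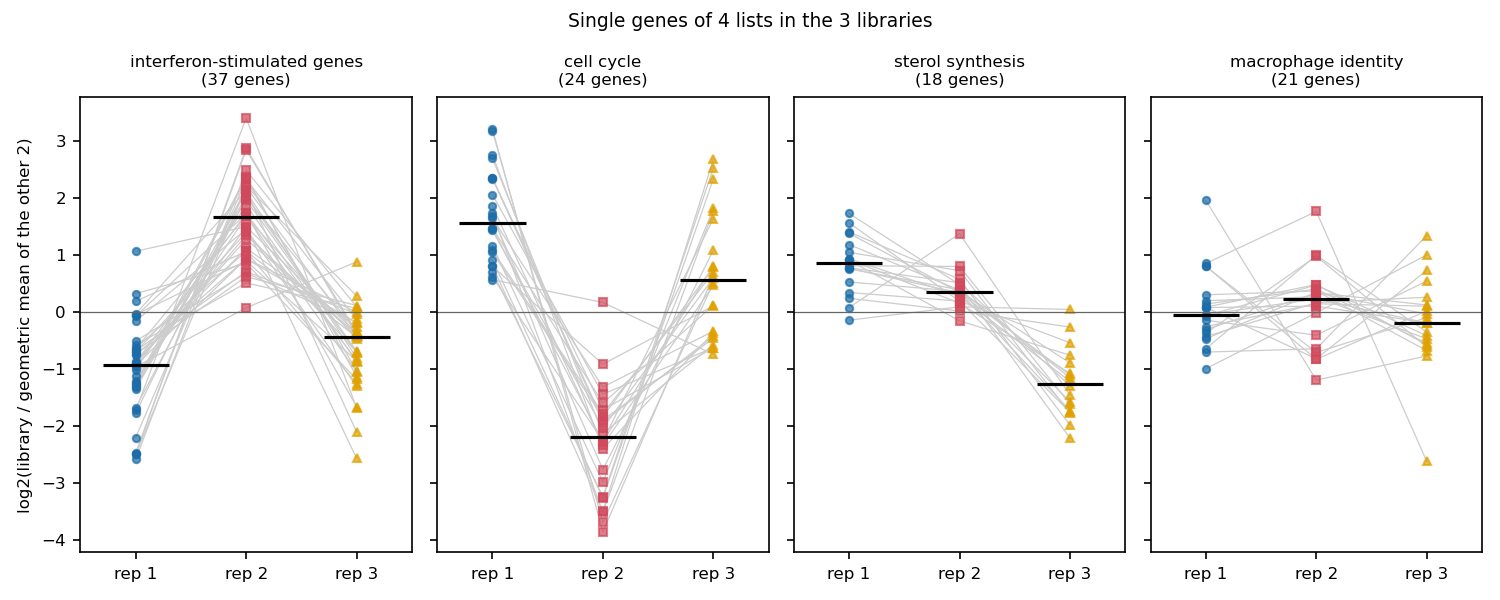
Log2 ratio of 1 library to the geometric mean of the other libraries for single genes of 4 lists, with grey lines joining the same gene across replicates 1, 2 and 3 and black bars marking medians. Nearly all interferon-stimulated genes lie highest in replicate 2 and nearly all cell cycle genes lowest there, while the medians of macrophage identity genes lie between -0.19 and 0.23.

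Each library came with 2 transcript tables, which made it possible to see how far the dominant transcript of a gene depends on the quantification. Among 7251 genes with at least 2 transcripts and at least 5 TPM in every library, the most abundant transcript was the same in both tables for 90.3%; by library this was 89.5% ± 0.543 (SD, n = 3). The same transcript was dominant in all 3 libraries for 78.1% of the genes in the RSEM-format table and 77.0% in the kallisto-format table. A protein-coding transcript was dominant for 92.9% and 92.1% of the genes.

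In the lipid A pathway, Tlr4-201 held 97.1% ± 2.36 of Tlr4 (n = 3) and Myd88-201 (chromosome 9, 119335934 to 119340041, minus strand) 99.67%, 98.2% and 99.1% of Myd88 in replicates 1, 2 and 3 (RSEM-format table). Il1rn, which encodes the interleukin-1 receptor antagonist, was led by Il1rn-201 (chromosome 2, 24345310 to 24350936) with 70.0% ± 3.21, and 70.2% ± 2.36 in the kallisto-format table. Rela-201 (chromosome 19, 5637483 to 5648130) held 77.4% and 85.1% of Rela in replicates 1 and 2 and 12.1% in replicate 3, where the retained-intron transcript Rela-203 held 43.8% and the non-coding Rela-207 42.5%. Irak2 was split between the coding Irak2-201 with 45.5% ± 11.3 and the retained-intron Irak2-207 with 38.0% ± 17.1. Irak2-201 led in replicates 1 and 2, and Irak2-207 led in replicate 3 with 56.6% against 36.2%. Nfkb1-206 held 41.0% ± 7.06 of Nfkb1 and Ikbkg-202 held 34.0% ± 16.5 of Ikbkg. In replicate 3 Ikbkg-202 held 15.3% and Ikbkg-216 led with 41.5%, while the kallisto-format table gave 35.05% and 34.66% there. Both tables put most of Ube2n on non-coding transcripts: the nonsense-mediated decay transcript Ube2n-205 held 36.0% ± 6.18 and Ube2n-204 held 34.2% ± 5.35, and Ube2n-204 led in the kallisto-format table with 38.9% ± 3.97. For Irf3 the tables differed by more than the spread between libraries: Irf3-201 (chromosome 7, 44997648 to 45002848, plus strand) held 35.5% ± 5.32 in the RSEM-format table and 10.2% ± 1.72 in the kallisto-format table, where the retained-intron Irf3-207 led with 23.4% ± 5.15.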

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

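The counts in this part were looked at only after the deposited values were seen, and no further test was run on them. They come from sequences outside the mouse genome, which none of the comparisons use, and they lie above the 3 counts that a count of 0 allows. The bacteriophage phiX174, whose DNA is commonly added to Illumina runs as a control, had 36595 expected counts in replicate 1, 36370 in replicate 2 and 45070 in replicate 3. The ERCC spike-in RNAs, a set of synthetic standards, had 9, 17 and 5 estimated counts in the kallisto-format tables of replicates 1, 2 and 3 and 0 in the gene tables. With 3 libraries in the group, no library was tested as an outlier.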

How the results depend on the processing

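The ratios of a list against 1 other library at a time and the removal of the GC and length trend were chosen after the results were seen; the other alternatives were planned. Values that moved beyond a set limit follow, and unless stated, the cause was not tested. For list medians, transcript agreement and the coefficient of variation the limit was the spread between replicates, taken for the coefficient as its jackknife standard error. Counts had a limit of 1.5 times, and list spreads and ratios the SD of matched lists. The count of variable genes was 146 without a low-count filter and 9 as DESeq2 dispersion outliers, and ran from 0 to 7 with a replicate left out. The biological coefficient of variation was 0.461 without the filter, 0.414 at a mean count of at least 50 and 0.382 to 0.406 with a replicate left out. Agreement of dominant transcripts was 89.7% at 1 TPM or more, 97.9% where the dominant share was at least 60%, and 89.4% to 89.99% with a replicate left out. The TLR4 median was 19.4 in FPKM, 31.3 TPM without mitochondrial genes, 27.0 TPM in the kallisto-format table and 25.3 to 32.7 TPM with a replicate left out. The early effectors had a median of 20.3 in FPKM, 23.6 TPM in the kallisto-format table and 23.0 to 38.5 TPM with a replicate left out; the late effectors had 0.370, 0.667 and 0.330 to 0.535, and 7 of their members reached 0.5 TPM in every library. The medians in FPKM are on another scale than those in TPM, as that unit is not rescaled to a fixed total.

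The spread of interferon-stimulated genes ran from 0.512 to 8.38 with a replicate left out and their ratio in replicate 2 from 1.51 to 1.56; the ratio was 1.80 and 1.86 with log2 TPM and pseudocounts of 1 and 0.1. Cell cycle genes had a spread of 6.71 at a mean count of at least 50 and of 1.25 to 11.2 with a replicate left out, and a ratio in replicate 1 of 0.71 to 2.73. The ribosomal protein ratio in replicate 3 was -1.16 with log2 TPM at either pseudocount, a scale on which the median of all tested genes of that library was -0.23, -0.69 with the GC and length trend removed, and -0.78 to -0.77 against 1 other library.

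The ratios that changed sign, among those over 2 SDs from the mean of matched lists, were these. On the log2 TPM scale the inflammasome list in replicate 3 was at -0.0228 and -0.0229 with pseudocounts 1 and 0.1 and megakaryocyte markers in replicate 3 at -0.00899 and -0.0205. Against 1 other library at a time the range was -0.35 to 0.0122 for negative regulators in replicate 1, -1.56 to 0.34 for interferon-stimulated genes in replicate 3, -0.00609 to 0.37 for the lysosome list in replicate 2, -0.27 to 1.12 for sterol synthesis in replicate 2, -0.71 to 1.75 for cell cycle genes in replicate 3, -0.098 to 1.53 for monocyte markers in replicate 2, -2.10 to 0.0929 for mitochondrially encoded genes in replicate 2, and -0.00392 to 0.78 for ribosomal proteins in replicate 1. Nearer to matched lists, 33 other ratios changed sign under at least 1 alternative (56 values), the TLR4 components in replicate 2 among them at -0.048 against replicate 3 alone. The count of detected genes stayed within 1.5 times under all 8 alternatives. Of the other values, 187 of 227 list medians moved by less than the SD of the library medians, and 98 of 114 list member counts stayed within 1.5 times. For 90 of 170 list spreads and 306 of 525 list ratios the move was below the SD of matched lists. Mean TPM values of single genes moved by less than their SD in 3298 of 3462 cases. Of these, 2085 had a replicate left out, which cannot move a mean of 3 libraries by its SD. The others were 564 of 695 means in the kallisto-format table and 649 of 682 without mitochondrial genes. No paired analysis was possible because there is 1 group. Depth limits genes near the floor, such as Il6 with 2, 7 and 10 counts.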

Other observations

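The tests of explanations in this part, and the ratios against 1 other library, were chosen after the patterns were seen; those on GC content and length and on MAPK/ERK targets were set before their own values were seen. There is 1 group, so no biological explanation was tested against a second condition.

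Other gene groups also moved together between replicates. Sterol synthesis genes were highest in replicate 1 for 16 of 18 members and lowest in replicate 3 for 17, with median log2 ratios of 0.86 (0.27 against replicate 2 alone), 0.35 (-0.27 in replicate 2 against replicate 1 alone) and -1.25; Fdps, which makes farnesyl pyrophosphate, was at 131, 89.5 and 21.8 TPM and Hmgcs1 at 93.2, 87.1 and 46.3 TPM. Lipid handling and LXR genes were highest in replicate 3 for 12 of 14 members (0.91), with Gpnmb at 8019, 9140 and 31374 TPM. Cytokine receptors, in contrast, were split, with 11 of 16 members lowest in replicate 1 and 5 highest there (-0.76).

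Some genes that overlap or copy others had unequal values between replicates or tables; they were chosen after their values were seen. Gm49369 (chromosome 7, 142371096 to 142382667, minus strand), which overlaps Ctsd and Ifitm10, was at 7.99, 18.9 and 4440 TPM in replicates 1, 2 and 3 (77.9, 95.2 and 5484 TPM in the kallisto-format tables) while Ctsd was at 13128, 14993 and 10887 TPM. The processed pseudogene Gm12715 (chromosome 4, 103563402 to 103564529) was at 59.97, 42.3 and 626 TPM (0.645, 0.681 and 495 TPM) and Rps6-ps4 (chromosome 2, 75191073 to 75191822) at 89.6, 77.3 and 583 TPM (546 TPM in replicate 3 and near 0 in the others), so both tables put these 3 genes highest in replicate 3. The mitochondrial gene mt-Co3 was at 857, 364 and 32.2 TPM in the gene tables and at 3466, 3963 and 3160 TPM in the kallisto-format tables.

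Interferon-stimulated genes were higher in replicate 2 by a median log2 ratio of 1.68. Removing the trend on GC content and length left 1.60, and the 14 members outside the multigene families had 1.42, against an SD of 0.17 for matched lists, so neither bias accounts for the whole pattern. Early effectors had a ratio of 0.39 (SD of matched lists 0.17), 0.49 with that trend removed, 0.83 against replicate 3 alone and 0.13 against replicate 1 alone, while interferon-stimulated genes had 1.56 and 1.51 against the same libraries. Against replicate 3 alone the early effectors lie above 0.5 of the ratio of the interferon-stimulated genes and in the other comparisons below it. The NF-kB list was at 0.88, and at 0.99 against replicate 3 alone, both above 0.5 of the matching ratio of the interferon-stimulated genes. With the trend removed the NF-kB list was at 0.61 and against replicate 1 alone at 0.64, both below that limit. Exposure to lipid A (a mislabelled time point) therefore cannot be told apart from other causes. Interferon made in the culture may also remain and was not tested. Replicate 2 was also the library with the fewest neutrophil and cell cycle transcripts.

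Cell cycle genes were higher in replicate 1 by a median log2 ratio of 1.56, and removing the trend on GC content and length left 1.55. The ratio of progenitor markers was -0.54 (0.20 against replicate 3 alone and -1.06 against replicate 2 alone), but with 4 tested markers, 2 of them at a mean of 1 TPM or more, cells left undifferentiated cannot be told apart from dividing macrophages. A younger or denser culture may also give such a pattern, and the labels give no value for it.

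Ribosomal protein transcripts were lower in replicate 3 by a median log2 ratio of -0.77, and removing the trend on GC content and length left -0.69. Against matched lists the ratio was -0.96, whereas dilution by mitochondrial transcripts would lower other nuclear genes alike. Their named pseudogenes summed to 2817 TPM in replicate 3, against 3358 and 3676 TPM in replicates 1 and 2, while the genes summed to 38551 TPM against 75782 and 82063 TPM, so reads moved to those 290 pseudogenes do not account for it. A difference in library preparation that acts on short transcripts by another route may remain and was not tested. Replicate 3 alone came from 4 read files, but that number does not tell how a library was prepared.

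A hypothesis for replicate 1 is stronger growth factor signalling through the MAPK/ERK pathway, as Dusp6 (113, 4.99 and 3.39 TPM), Etv5 (80.0, 5.40 and 7.03 TPM) and Ccnd1 (377, 15.2 and 39.9 TPM) were highest there; the 3 genes were chosen after their values were seen. The other targets of the pathway were then tested, without these genes. Of 13 listed targets 8 were tested, all 8 were highest in replicate 1, and their median log2 ratio was 2.12, against 0.10 ± 0.30 (SD) for matched lists. Spred1 was at 60.3, 19.0 and 16.02 TPM and Dusp4 at 22.0, 4.09 and 3.23 TPM. The 8 targets go with the hypothesis, which was found and tested on the same libraries. Immediate early genes, a list fixed beforehand, did not rise with them in replicate 1. Their median log2 ratio there was -0.06 (-0.59 to 0.26 against 1 other library at a time), with 3 of 15 tested members highest and 6 lowest. Ccl2 and Ccl7 were also highest in replicate 1.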
